A study of Caenorhabditis elegans with 2 samples.

How the data were processed

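Total RNA of adult whole worms, 1 wild-type and 1 mir-249 knockout sample, was extracted with Tri-Reagent, treated with DNase and made into small RNA libraries with a ScriptMiner kit from 5 µg of RNA, with tobacco acid pyrophosphatase applied between the 3' and the 5' adaptor ligation and 18 cycles of PCR, per the labels' protocols. The deposited values are estimated counts of reads per position and strand, in genome build ce6 per the file headers, in which each read appears divided among its genomic positions. That division is not stated and was read from the values, which were whole numbers or simple fractions of them; 82.7% of wild-type and 83.3% of mutant positions were whole within a tolerance of 1e-06, and these carried 92.9% of the reads in both. Every interval spanned 22 nt, and no position was listed more than once per strand. The aligner, the adapter trimming and the rule by which reads of this length were chosen are not given in the sources used here. Totals are those of this read class, not of whole libraries, so RPM values are scaled to the reads of this class. A whole-number value usually comes from reads with 1 position, but a shared read count can also divide evenly, so the alternative for single-position reads kept whole-number values. PCR reads without molecular identifiers are not independent molecules.

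Gene names came from the Ensembl annotation of WBcel235, another build than ce6, paired by sequence name with RefSeq symbols of the same assembly; 22169 of 22407 genes of the 4 types used (coding, pseudogene, long intergenic and antisense RNA) had a pair. No coordinate was converted. Instead the displacement between the builds was measured: in windows of 100000 nt, the offset was taken at which most antisense reads lay inside coding exons and fewest crossed an exon edge. Over 806 windows with at least 500 positions and a score of at least 0.3 per position it ranged from -6 to 122 nt, except on chromosome V from 19.7 Mb on, where it was 4612 to 4614 nt. In all 815 of 1005 windows could be scored. Genes were then counted over cores, the gene span without 150 nt at each end and without positions within 150 nt of any other gene, so that a displacement of up to 150 nt cannot move a read into another gene. In windows that could not be scored the displacement is unknown. Genes on chromosome V that ended later than 200 kb before the jump were left out, as were cores under 50 nt; 20134 genes had a core. Exons, as first planned, and microRNA arms were not used because the builds differ, and first bases were not analysed here. MicroRNA reads are sense reads within 150 nt of the hairpin.

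Counts were rounded to whole numbers for intervals only. Ratios are of RPM; log2 ratios have a pseudocount of 0.5 reads. Intervals of ratios and shares are exact Clopper-Pearson 95% intervals, for ratios conditional on the sum of both counts; a count of 0 was given a floor of 3 reads. With 1 library per group no test was made and no p-value is given. The size rule asked for at least 100 reads over both libraries, a log2 ratio of at least 1 or at most -1 and an interval that excluded 1. Lists of genes, fixed before the data were examined, were described by the median log2 ratio of members with at least 20 reads and its percentile among 10000 lists in which each member was replaced by a gene within 50 ranks in reads; the central range runs from percentile 2.5 to 97.5. The lists were ERGO-1 class targets, mutator class loci, the pair of microRNA-primed loci, spermatogenesis, major sperm protein, germline, histone, small RNA pathway, muscle, intestine, cuticle, neuron and ribosomal protein genes, and the let-7, mir-35, mir-58, mir-51 and other microRNAs.

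The genes named were fixed by a rule: mir-249, ZK637.6, mir-243 and Y47H10A.5, the 12 genes with the largest and the 12 with the smallest log2 ratio past the size rule, the 5 genes and 5 microRNAs with most reads, and the members of each list with most reads. In simulated counts for the 6091 genes, with 200 genes changed, the rule called 50% of genes changed 2-fold and 2% of those changed 1.5-fold. A 2-fold change lies at the limit of the rule and a 1.5-fold change inside it, so these shares follow mostly from the limit. The rule called 92% of genes changed 4-fold. It called 84% of those changed 8-fold, of which 8 of 50 had dropped below the count minimum. Among 5891 unchanged genes it called 0, and 73 had dropped below the count minimum. That simulation held counting error only. Alternatives were another scaling, whole-number values, distinct positions, both strands, other count minimums and another pseudocount, with wider margins and 1 kb windows added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.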

Results

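Small RNAs of adult whole worms of Caenorhabditis elegans were compared between 1 wild-type library and 1 library of a mir-249 knockout mutant. The RNA had been treated with tobacco acid pyrophosphatase, which turns the triphosphate at the 5' end of secondary siRNAs into a monophosphate that the adaptor can be ligated to. The deposited data held 6229435 reads at 1420022 positions for the wild-type library and 6216364 reads at 1423972 positions for the mutant library, all with a length of 22 nt. With 1 library per group there was no replicate check. Each ratio below therefore compares these 2 libraries, not the genotypes, and every interval is an exact 95% interval that covers counting error only.

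The targeted microRNA was examined first as a check of the labels. On the sense strand within 150 nt of the mir-249 hairpin, 1 read was found in the wild-type library and 0 in the mutant library, and the floor of 3 reads corresponded to 0.482 reads-per-million units (RPM) in the wild-type and 0.483 in the mutant library. Both libraries were below that floor, so the labels could not be checked with mir-249. MicroRNAs as a class were nearly missing from these reads, whose selection rule is not stated, so a count of 0 does not speak to the level of a microRNA: only 117 of 261 hairpins had a read in either library. The let-7 family, which times the passage from larva to adult, had 0 reads in both libraries at all 4 hairpins, and mir-243 had 0 reads in each. The hairpins with most reads were mir-257 with 1687 reads in the wild-type and 1358 in the mutant library, mir-262 with 1011 and 872, and mir-260 with 634.5 and 1041.5, followed by mir-258.1 and mir-258.2, copies with the same values of 708 and 649 reads each, whose reads were therefore shared. As the reads lay anywhere within 150 nt, they need not be microRNAs. The hairpin mir-8191, named after its values were seen, had 83.25 reads in the wild-type and 0 in the mutant library, below the count minimum. None of the 10 hairpins with at least 100 reads passed the size rule, which asked for a log2 ratio of at least 1 in either direction and an interval that excluded 1.

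The other microRNA lists were as thinly covered. Reads near the mir-35 family, microRNAs of oocytes and embryos, numbered 18 in the wild-type and 22 in the mutant library, and its member with most reads was mir-41 with 12 and 19 reads. The mir-58 family had 5 and 3 reads over the 4 hairpins examined, which did not include mir-58.2 with 4 and 2 reads. The mir-51 family had 1 and 5. The list of other tissue and stage microRNAs had 511 and 543 reads, of which mir-232 held 461 and 491.

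The libraries were made to detect secondary siRNAs. ZK637.6 was examined as a target of miR-249, a link taken from background knowledge and not from the labels. ZK637.6 (WBGene00014987) is annotated as a pseudogene on chromosome III, and the antisense reads counted in its trimmed interior lay between 8898772 and 8899401 in ce6 coordinates, with further reads on that strand next to it. Antisense siRNAs were present in both libraries: 323 RPM in the wild-type and 292 in the mutant library, from 2011.5 and 1813.5 reads at 156 and 158 distinct positions. Over that interior, the mutant-to-wild-type ratio was 0.903 (0.847 to 0.963), a log2 ratio of -0.15. Antisense reads before the interior were lower in the mutant library too. The bin that starts at 8898500 had 48.6 RPM in the wild-type and 32.5 in the mutant library, and that at 8898600 had 27.5 and 21.7. The interior may therefore understate the difference at the whole locus, for which no ratio was computed. The rank and the distinct positions given here cover the interior only. Of 495 genes with between 0.5 and 2 times as many reads, 22.02% had a lower log2 ratio and 44.2% lay at least as far from 0. When distinct positions were counted in place of reads, the log2 ratio was 0.01, with the opposite sign. As 156 and 158 positions held 2011.5 and 1813.5 reads, a modest fall in reads need not change the number of positions. The position count therefore cannot tell whether reads fell.

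**Figure D1:**
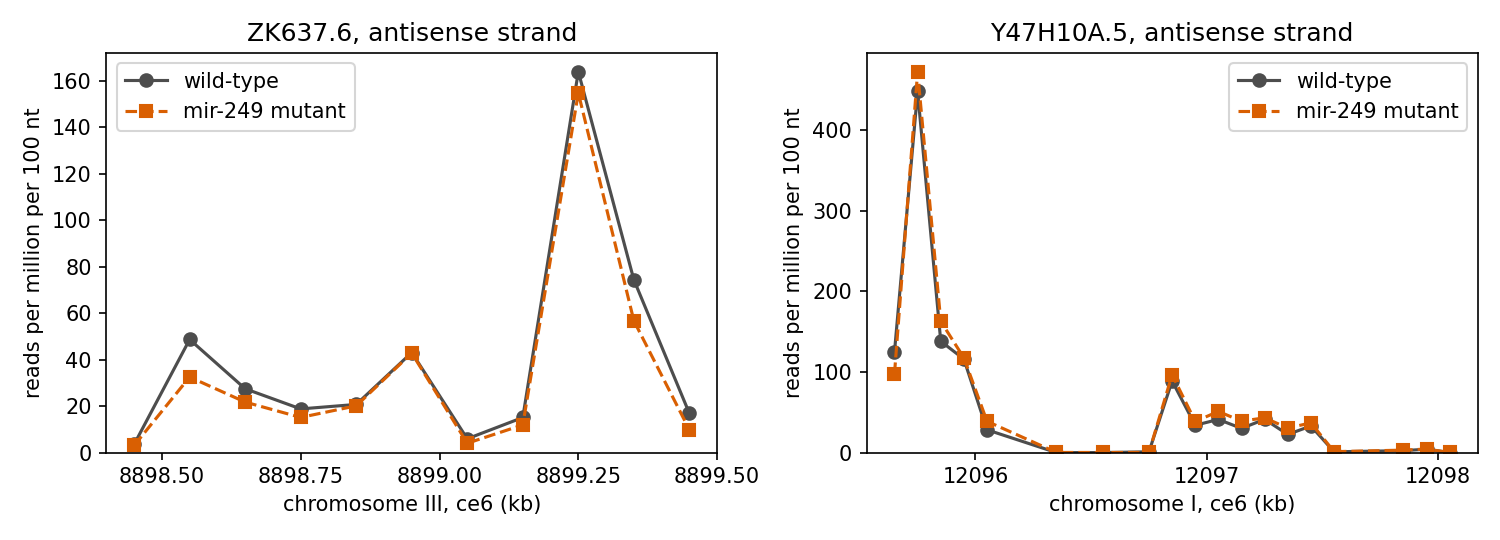
Antisense RPM in bins of 100 nt along ZK637.6 (left) and Y47H10A.5 (right), with ce6 positions in kb on the horizontal axis; circles are the wild-type library and squares the mir-249 mutant library. Bins reach past the trimmed interiors that were counted; all 11 bins of ZK637.6 with at least 1 RPM in the wild-type were lower in the mutant, and 13 of 14 bins of Y47H10A.5 were higher.

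Y47H10A.5 (WBGene00012961), where siRNAs are primed through miR-243 and RDE-1, was measured in the same way as a locus that should not need mir-249. The antisense reads counted in its trimmed interior lay on chromosome I between 12095633 and 12097523 (ce6). It had 1145 RPM in the wild-type and 1223 in the mutant library, at 378 and 428 distinct positions. The ratio was 1.07 (1.03 to 1.10), a log2 ratio of 0.10, and 53.5% of 114 genes with a similar number of reads lay at least as far from 0. The list of these 2 loci had a median log2 ratio of -0.03, at percentile 47.2 of random lists. As it joins a target with a locus that should not need mir-249, that median does not speak to either.

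Most reads were antisense to genes. Reads antisense to gene interiors made up 57.5% (57.5 to 57.6) of the wild-type library and 58.4% (58.3 to 58.4) of the mutant library, a ratio of 1.01. Sense reads made up 2.62% and 2.499%. Antisense reads of long intergenic RNAs took 2.09% of the wild-type and 2.45% of the mutant library, and most of that difference lay at linc-22 and linc-29. The genes with most antisense reads were linc-22, with 7032 RPM in the wild-type and 9107 in the mutant library, linc-29 with 6194 and 7614, got-1.2 with 5072 and 5162, W03H9.2 with 5276 and 4885, and bath-45 with 4998 and 4697. At linc-22 only 50.8% of the reads came from whole-number values, so many reads had several genomic positions and its ratio of 1.30 is uncertain. Chromosome X held 10.7% of the wild-type reads and 11.3% of the mutant reads, a ratio of 1.06 (1.06 to 1.07). The gene linc-22 lies on X, with 43805 of 664336 reads in the wild-type and 56613 of 704154 in the mutant library. A ratio of X without linc-22 was not computed.

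Across the 6091 genes with at least 100 antisense reads, the 2 libraries were close for most genes and far apart for a few. The median log2 ratio was 0.05, and 91.6% of genes lay within 0.5 of 0 on the log2 scale. The size rule was passed by 37 genes with more reads in the mutant library and by 70 with fewer. The interval excluded 1 for 25.4% of genes, against the 5% that counting error alone gives, so the libraries differed by more than counting error. How much of this is the usual spread between worm samples was not measured. All 37 higher genes had more distinct positions in the mutant library, and 69 of the 70 lower genes had fewer. These genes were chosen by their reads in the same 2 libraries, and more reads tend to fill more positions. That agreement is therefore largely what the choice of genes would give. With distinct positions in place of reads and a minimum of 100 positions, 4 of 4852 genes were higher and 13 lower. That minimum left out genes past the read rule, such as Y102A5C.36 with 31 and 57 positions. A position also counts once however many reads it holds, so these counts of genes are not like those by reads.

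The largest ratio was that of Y102A5C.36, with 14.3 RPM in the wild-type and 124 in the mutant library, 8.67 times as many (6.95 to 10.9). The gene gfrl-1 followed with a ratio of 7.37 (6.296 to 8.64), then R13H4.5 with 4.92, the nuclear hormone receptor gene nhr-61 with 4.65, ZC204.14 with 3.74 and the pseudogene W06A11.4 with 3.48. The other genes with the largest ratios were the chemoreceptor gene srab-11 with 3.39, the lactate dehydrogenase gene ldh-1 with 3.35, anr-24 with 3.32, fbxa-46 with 3.21, the pseudogene Y17D7C.3 with 3.14 and F40H3.6 with 2.98. Y17D7C.3 had the most reads among these, 280 RPM in the wild-type and 880 in the mutant library, at 215 and 310 distinct positions. At ZC204.14 and anr-24, 47.98% and 12.6% of reads came from whole-number values, so their ratios are uncertain.

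Among genes with fewer reads in the mutant library, the pseudogene Y82E9BR.7 on chromosome III had 177 reads in the wild-type and 0 in the mutant library. With the floor of 3 reads in place of 0 it was 58.9-fold lower, and the exact interval of the fold began at 47.4. The macrophage migration inhibitory factor homolog mif-1 had 24.4 RPM in the wild-type and 1.29 in the mutant library, 18.96 times fewer. The ciliary gene dyf-3 had 362 and 46.7 RPM, 7.75 times fewer (6.85 to 8.79), at 294 and 122 distinct positions. The hedgehog-related gene wrt-5 was 13.2 times lower, B0457.4 6.59 times, Y48G9A.7 6.14 times and C28A5.6 5.77 times. The histone genes his-43, his-61 and his-57 had 25.2, 14.3 and 5.85 times fewer reads, but histone genes have near-identical copies, and only 11.9% of the reads at his-43 and 23.8% at his-57 came from whole-number values, against 96.3% at his-61. F42G4.6 and Y81G3A.1 were 9.73 and 8.26 times lower, with 48.7% and 63.3% of reads from whole-number values.

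**Figure D2:**
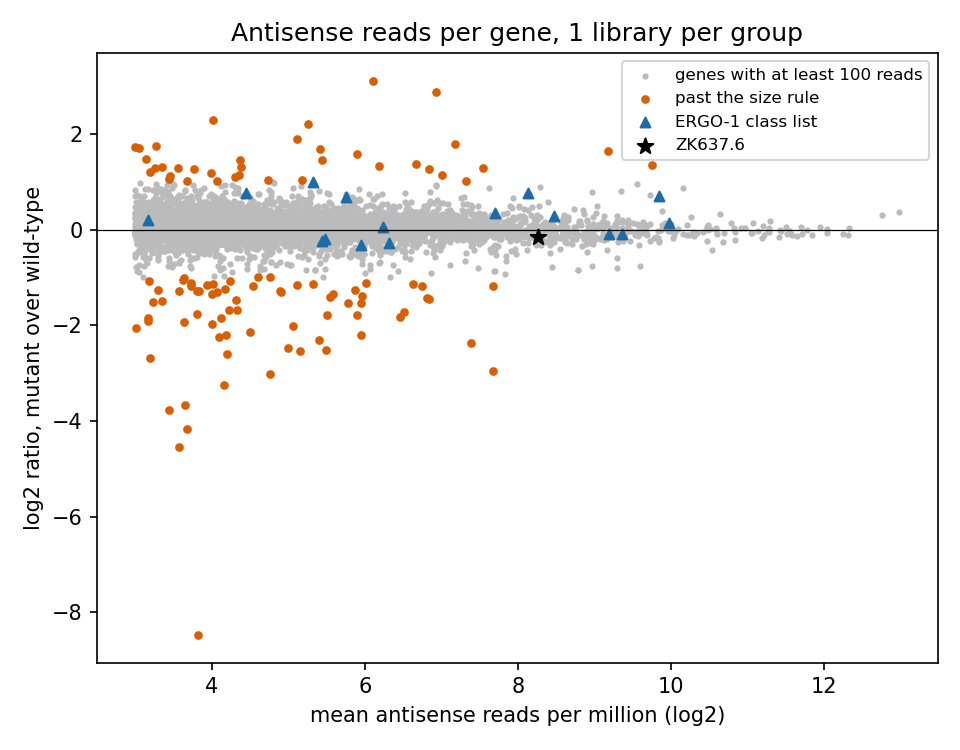
Log2 ratio of antisense reads, mutant over wild-type, against the mean RPM (log2 axis) for the 6091 genes with at least 100 reads. Orange points are the 37 genes above and the 70 genes below the size rule, triangles are members of the list of ERGO-1 class targets with at least 100 reads, and the star is ZK637.6 at -0.15; the lowest point is Y82E9BR.7, whose 0 mutant reads place it by the pseudocount alone.

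Of the lists fixed before the data were examined, the targets of the ERGO-1 class of siRNAs stood apart. ERGO-1 is an Argonaute that acts in the oogenic germline and embryo upstream of secondary siRNAs. The 21 measured members had a median log2 ratio of 0.35, at percentile 100 of random lists matched on reads, whose central range went from -0.09 to 0.14. No member passed the size rule; Y17D7C.2 had a ratio of 4.41 (1.63 to 14.9) on 5 and 22 reads, below the count minimum. The interval lay above 1 for 11 members, below 1 for 4 and included 1 for 6. E01G4.5 had 699 RPM in the wild-type and 1132 in the mutant library, a ratio of 1.62 (1.56 to 1.68), while E01G4.7 had a ratio of 1.09, and K06B9.6 and C36A4.11 had 0.939 and 0.942. Several members are paralogs with shared reads, such as ZK402.3 and ZK402.5, so members are not independent. The median was 0.17 over members with at least 100 reads, and 0.06, inside the range of random lists, when distinct positions were counted in place of reads.

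The medians of the other siRNA and germline lists lay inside the range of random lists. Loci of the mutator-dependent class had a median of 0.03 over 11 members, at percentile 75.5, with 4 intervals above 1, 4 below and 3 that included it. Its members with most reads were linc-22 and linc-29, both higher in the mutant library, then eri-6 with a ratio of 1.04 and F15D4.5 with 0.942. Members lay apart: Y20F4.4 and R06C1.4, named after their values were seen, had ratios of 1.75 and 0.574. Genes of the oogenic and general germline had a median of 0.03 over 39 members, at percentile 26.2, with 30 intervals that included 1; glh-1, a helicase of germ granules, had 245 and 230 RPM, the germ granule gene pgl-3 186 and 167, and the yolk receptor rme-2 164 and 184. Genes of the small RNA machinery had a median of 0.03 over 36 members, at percentile 35.2. The nuclear Argonaute hrde-1 had a ratio of 0.974 and the double-stranded RNA channel sid-1 1.02. A size factor from the median ratio lowers every log2 ratio by 0.05 and so puts each of these 3 medians at -0.02. Spermatogenesis genes had a median of 0.26 over 4 members, at percentile 91.8, but 0.031 over both strands and 0.099 over distinct positions, with spe-41 at 1.02 and fer-1 at 0.777.

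Muscle genes had a median of 0.14 over 9 members (percentile 75.6), with unc-45 at a ratio of 1.10 and lev-11 at 0.848. Intestine and yolk genes had 0.48 over 5 members (percentile 88.2), with vit-6 at 1.002 and vit-1 at 1.09. All 5 intervals included 1. The median was -0.09 over reads from whole-number values, 0.58 over distinct positions and 1.06 over both strands, the last pair outside their ranges. Neuron genes had 0.18 over 9 members (percentile 80.2), with egl-21 at 0.853 and unc-119 at 1.13. The neuron median was 0.32, outside its range, over distinct positions and 0.028 over members with at least 100 reads. Ribosomal protein genes had -0.02 over 31 members (percentile 8.71), of which 29 had intervals that included 1, with rps-14 at 1.005 and rps-4 at 1.07. The list of replication-dependent histone genes had -0.19 over 7 members (percentile 13.5), with his-24, a linker histone, at 0.946 and his-4 at 0.777, and -0.44, outside its range, over reads from whole-number values. Of the 13668 wild-type reads of the histone list, 13459 were those of his-24, and no other measured member had more than 40.1. The median of that list therefore says little about histone genes as a family. The genes his-43, his-61 and his-57, lower in the mutant library, are not on that list. No major sperm protein gene and no cuticle gene of the lists reached 20 reads. No member of any list passed the size rule.

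**Figure D3:**
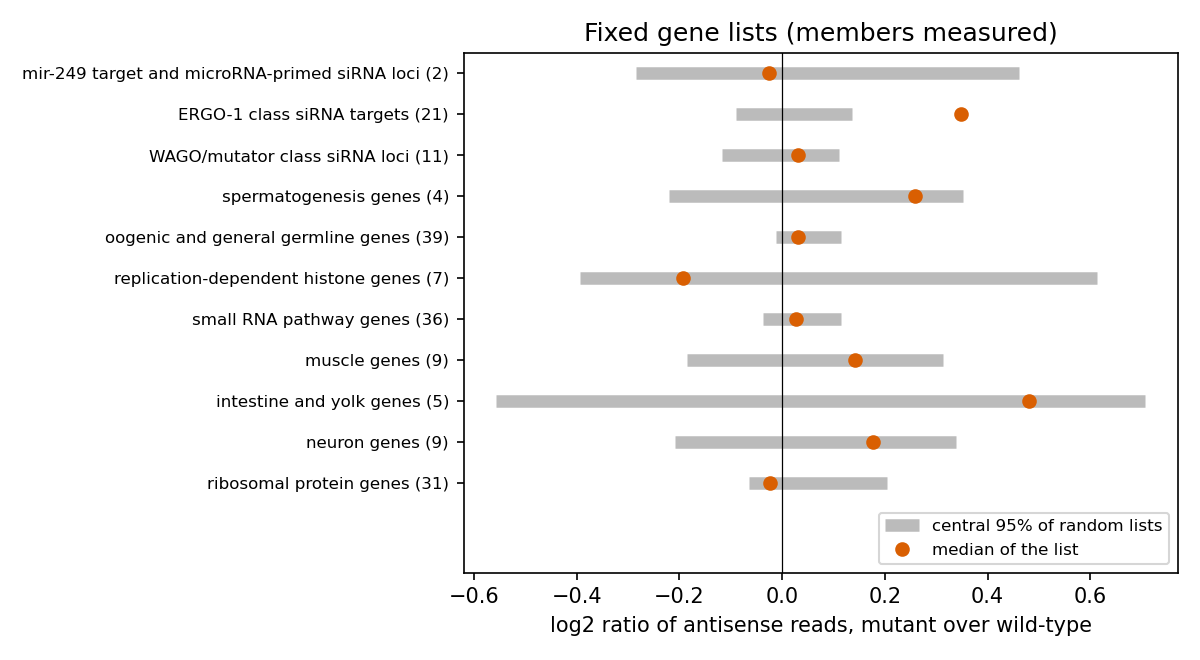
Median log2 ratio of antisense reads, mutant over wild-type, for each fixed list (orange points) with the central range of the medians of 10000 random lists matched on reads (grey bars); the number of measured members stands in parentheses. The median of the ERGO-1 class list, 0.35, lies above its range and the other medians lie inside theirs.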

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

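The tests in this part, and the limits that picked its places, were chosen after the result was seen. A place needed at least 1000 reads over both libraries, a log2 ratio of at least 3 and under 10% of its mutant reads in counted gene interiors. These limits were met by 2 places, and places with smaller ratios or fewer reads were also seen, such as chromosome II from 2094000 to 2095999 (ce6, plus strand) with 161 reads in the wild-type and 1128 in the mutant library. On the minus strand of chromosome III between 8854000 and 8858999 (ce6), the mutant library had 4763 reads and the wild-type library 388, a ratio of 12.3 (11.09 to 13.7). On the minus strand of chromosome V between 19958000 and 19958999 (ce6), the mutant library had 938 reads and the wild-type library 93, a ratio of 10.1. The place on chromosome III lay outside counted gene interiors but for under 10% of its mutant reads; that on chromosome V lay in the part where no genes were counted, so its position relative to genes is not known here.

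For the stretch on chromosome III, over-amplification of a few sequences would leave the number of positions alike, but distinct positions had a ratio of 5.61 (4.698 to 6.74), 145 in the wild-type and 816 in the mutant library. Reads shared with other copies are argued against because 100% of the mutant reads there came from whole-number values, which reads split among copies seldom give. A difference in depth could not give this ratio, which was already scaled to the reads of each library, so depth was not tested. Nearby reads on the same strand did not share the difference. From 8860000 to 8864999 the ratio was 0.862 (0.820 to 0.905). From 8852000 to 8853999 it was 1.12, with an interval that included 1. The genotype and the strain background stay open and were not tested, as 1 library per group cannot separate them.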

How the results depend on the processing

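With distinct positions in place of reads, the log2 ratio of ZK637.6 was 0.014 and so changed sign, and that of Y47H10A.5 was 0.17. Of the 4852 genes that kept the minimum, 4 were then higher and 13 lower. With distinct positions 2 lists lay outside their range, intestine and neuron genes, without the ERGO-1 class. The cause of these shifts was not tested. Every setting that counted reads left ZK637.6 lower in the mutant library. Its log2 ratio was -0.198 with the median-of-ratios size factor, -0.149 with whole-number values and -0.146 over both strands. It was -0.147 when scaled to reads that are not sense microRNA, and -0.176 with doubled margins, chosen after the data were seen. The count minimum set the number of genes by construction: 101 higher and 137 lower at 20 reads, 14 and 21 at 500, and 132 and 190 at 1 read. For microRNAs it gave 4 hairpins at 20 reads and 5 at 1 read. Both microRNA counts include mir-2209.1 and mir-2209.3, each with 44 reads in the wild-type and 18 in the mutant library. As their values are the same, these hairpins may hold the same reads and need not be separate differences. The median-of-ratios size factor gave Y47H10A.5 a log2 ratio of 0.044. Lists outside their range numbered 2 with whole-number values (histone genes added) and 2 with both strands (intestine genes added). Scaled to sense microRNA reads, mir-249 was at 141.6 RPM in the wild-type, from the same 1 read. Of alternatives chosen after the data were seen, doubled margins gave Y47H10A.5 0.14, 1 kb windows gave 129 higher and 187 lower, and whole-number values gave a composition ratio of 1.01. The cause of the other shifts was not tested. Of all values that answer a comparison, 31 stayed, 20 moved and 1 changed sign. A count stayed if it was within a set fold of the main count, any other value if it was inside the main interval. The ERGO-1 class median ranged from 0.06 to 0.44 over 8 alternatives. Reads by first base, the mature arm of mir-249, exons and another class order were not run. No paired analysis was possible because each group has 1 library.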

Other observations

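The genes named here, the tests of the stretch without mutant reads and the use of the mir-35 family as a test were chosen after the results were seen, as was the reading of the median over whole-number values, itself set before the data were examined, as a test for paralogs. Sense reads of genes also differed between these 2 libraries. Of 293 genes with at least 100 sense reads, 3 were higher and 9 lower in the mutant library by the size rule. Sense reads at snpc-3.1, snpc-3.2, snpc-3.3 and F18A11.6 numbered 425, 393.5, 485 and 413 in the wild-type and 13.8, 12.8, 14.8 and 14.5 in the mutant library. Only 7.48% to 20.8% of these reads came from whole-number values, so the 4 genes share reads and do not count as separate differences. With 100% of reads from whole-number values, T23G11.1 had 138 sense reads in the wild-type and 41 in the mutant library. The F-box gene fbxa-192 had 425 sense reads in the wild-type and 1274 in the mutant library, a ratio of 3.01 (2.69 to 3.36), with 31.1% of reads from whole-number values. On the plus strand of chromosome IV between 7485000 and 7486999 (ce6), where the reads counted at his-61 lie, the wild-type library had 2588 reads and the mutant library 105. The ratio there was 0.041 (0.033 to 0.049), a log2 ratio of -4.61.

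Between 1355354 and 1364969 on the minus strand of chromosome III (ce6), a stretch of 9.62 kb that holds the 177 antisense reads of Y82E9BR.7 and the 260 sense reads of Y82E9BR.8, the wild-type library had 1084 reads from whole-number values at 364 positions and the mutant library 0. Counting error alone is argued against by 100 random deals of the reads to the libraries, in which no stretch anywhere held more than 25 reads. The deals treat reads as independent, and the next real stretch held 173 wild-type reads, so spread between libraries beyond counting error was not tested. Lines left out of the mutant data are argued against by 11 mutant positions inside the stretch, all with fractional values, from reads with several genomic positions. Sequence missing or altered in the mutant strain may account for it, but the other strand held 1 wild-type read from a whole-number value, too few to tell missing sequence from missing siRNAs.

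The higher reads of the ERGO-1 class list were weighed against 3 explanations. Reads shared between paralogs are argued against by the median over reads from whole-number values, 0.23, above the range of random lists (-0.07 to 0.15). Over-amplification of a few sequences is argued against by the median without the 5 positions with most reads in each gene, 0.27, above a range of -0.10 to 0.15, although the median over distinct positions, 0.06, was inside its range. More embryos in the mutant sample could raise these reads. Reads near the mir-35 family had a ratio of 1.22 (0.627 to 2.42), but they were few and need not be microRNAs. MicroRNAs were also nearly missing from this read class, so that ratio cannot show the number of embryos, and this explanation stays open. The genotype stays open and untested.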
